A study of Mus musculus with 6 samples.

How the data were processed

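RNA-seq was run on 3 mutant and 3 wild-type samples of sorted AT2 cells. Per the labels' protocols, total RNA was isolated with a column kit, mRNA libraries were made with a TruSeq kit, and all samples were sequenced together on 1 flow cell. The sequencer is given as an Illumina NextSeq500 in one label and as a HiSeq4000 in the series' design text. The labels give the time as 10 days after injury, and the extract protocol also mentions 8 days of culture, so whether the sorted cells were cultured before RNA isolation is not settled by the labels. The genome build named in the submitters' processing notes is mm9, and the tools named there are CASAVA and DESeq2, without versions. The aligner, the counting program, the gene annotation and the handling of strand are not given in the sources used here. Genes that overlap, antisense pairs and near-identical paralogs can therefore share reads. The deposited values were whole-number counts per gene symbol, not normalized, 1 file per library, and no row without a gene name was present. No coordinates are printed, because the counts are on mm9 and the gene annotation used here for names and for the order of neighbouring genes was RefSeq on GRCm38.

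Groups came from the sample titles. Of 515 genes in the fixed lists, 8 were matched through an older symbol and 4 were not matched. Genes were filtered with filterByExpr by group, which left 12899 genes holding at least 99.65% of the counts of each library. Counts were scaled by TMM and tested with edgeR's quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3, robust off, two-sided, mutant minus wild type), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 5%. Standard errors and 95% intervals of log2 fold changes came from the same fit. Gene values in the text are TMM-normalised CPM with the SD over 3 libraries, and sums over marker lists, values of single marker genes per library and sex-linked genes are CPM of the library total. Library totals of 22511461 to 30695994 counts put 3 counts at 0.0977 to 0.133 CPM, the floor for a gene with no counts. Such floors cover counting error only, since the reads carried no molecular identifiers.

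Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and a mean-variance trend, with adjustment over the 29 lists that had at least 3 tested genes. The basal, neuroendocrine, neutrophil and erythroid lists had fewer and were described as sums. Camera with a correlation estimated from the residuals and fry were run beside it. The gene lists, the tests and the rule for named genes were set before the data were examined. The rule named Dlk1, 12 core genes, the 10 genes with the largest change in each direction among those past the threshold or, where none passed, the 5 with the smallest p in each direction, and up to 4 members of each list with the smallest p. Where the text names a gene outside this rule, it was chosen after its values were seen. In the report these are the DESeq2 calls Entpd1, Dusp4 and Trpv6, and Dlk2, Xist, Ddx3y, Scgb1a1, Lyz1, Lyz2 and H2-Eb1.

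Replicates were compared by chi-square tests of their counts, which gave 18.4 to 76.7 per degree of freedom for pairs within a group, so no pair agreed within sampling noise. Both groups carry the numbers 1 to 3. The deviations of same-numbered mutant and wild-type libraries from their group means correlated at 0.31, 0.21 and 0.17, each above 0.1, so by the rule used the numbers paired the samples. This pairing comes from the data alone, since the labels give no shared day, litter or batch. A fit with the number as a block was an alternative.

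Alternatives were DESeq2's size factors and upper-quartile factors in edgeR, no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with sample quality weights, robust dispersion, the replicate block, an estimated correlation and fry for lists, and leaving out each library in turn. The 41 further markers of lung and blood cells and the 38 markers of tissues outside the lung were chosen after mutant 1 was seen to differ. This was before their own values were looked up, except for some that were also DESeq2 calls high in mutant 1. Alternatives added after seeing the data left out mutant 1 and wild type 2 together and ran DESeq2 without these libraries. The edgeR procedure was tested on simulated counts for the 12899 genes with the means and spread of these libraries and 200 changed genes, in 5 runs. It recovered 16.1% of genes changed 1.5-fold, 54.6% of those changed 2-fold and 78.8% of those changed 4-fold at the 5% threshold, with 6.2 false calls on average among 105.6. The camera procedure recovered a simulated shift of 0.5 (log2) in the AT1 list in 5 of 5 runs and called 0.6 of the 28 other lists on average. That shift was larger than the AT1 median of 0.19 in these data. With the real counts, splits of the libraries other than the real one called 8 to 20 lists. The simulated figure is therefore no measure of false list calls in these libraries.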

Results

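The data were gene counts from polyadenylated RNA of mouse alveolar type II (AT2) cells, the surfactant-making cells of the alveolus that also act as progenitors of the flat alveolar type I (AT1) cells. AT2 cells carried a tamoxifen-inducible Cre under the surfactant protein C promoter and a red Tomato reporter, and Tomato-positive cells were sorted by flow cytometry 10 days after lung injury with the bacterium Pseudomonas aeruginosa. The mutant mice carried in addition a floxed Dlk1, a gene for a membrane protein related to the Delta ligands of Notch receptors, and the wild-type mice did not. There were 3 libraries per group, 6 in all. The labels name separate samples but do not state that each came from its own animal, so the p-values measure the spread between these samples. The library totals were 30695994, 23718958 and 28332792 counts in mutants 1, 2 and 3, and 22511461, 25332204 and 24927932 counts in wild types 1, 2 and 3. Every library held counts for the same 23337 gene symbols.

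The targeted gene was examined first. Dlk1 had 2, 0 and 0 counts in the mutant libraries and 2, 0 and 2 counts in the wild-type libraries, all below the floor of 3 counts that a zero allows. No fold change can be given at this depth, and the Dlk1 counts did not check which libraries carried the deletion. With at most 2 counts in wild-type libraries of 22511461 to 25332204 counts, the wild-type cells held almost no Dlk1 transcript when sampled. Whether they held more at another time was not measured. The symbol-level counts also do not separate the floxed exons from the rest of the gene. Its relative Dlk2 had at most 5 counts in any library.

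AT2 transcripts were abundant in all 6 libraries. Sftpc, the surfactant protein C gene, made up 4.72% ± 0.19 of all counts in the mutant libraries and 5.15% ± 0.23 in the wild-type libraries (SD, n = 3 each). The summed level of the 20 AT2 markers ran from 176110 CPM (counts-per-million) in mutant 1 to 225237 CPM in wild type 1. Markers of other cell types were low in 5 libraries and high in mutant 1. Scgb1a1, the main secretory protein of airway club cells, stood at 7223 CPM in mutant 1 and at 309 to 542 CPM in the other 5. The pan-leukocyte gene Ptprc stood at 141 CPM against 2.09 to 7.59 CPM, and the fibrillar collagen gene Col1a2 at 54.6 CPM against 0.18 to 1.73 CPM.

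As sums over the marker lists, mutant 1 exceeded the mean of the other 5 libraries 14.5-fold for club and goblet cells (9182 CPM against 635 ± 139 CPM, SD, n = 5), 35.2-fold for fibroblasts, 39.8-fold for neutrophils, 12.1-fold for mesothelial cells, 8.29-fold for lymphocytes, 7.31-fold for genes of all blood cells, 3.68-fold for ciliated cells and 1.65-fold for endothelial cells. Erythroid transcripts summed to 342 CPM in mutant 1 and to between 1.28 and 10.1 CPM elsewhere, with 2 genes detected. Basal cell markers, with 2 detected genes, summed to 8.27 CPM in mutant 1 and 0.72 to 2.67 CPM in the others, and neuroendocrine markers, with 1 detected gene, to between 1.77 and 2.83 CPM in all 6. The macrophage and monocyte sum was lower in mutant 1 (2509 CPM against 4582 ± 999 CPM). Most of it was Lyz1, a near-identical paralog of the AT2 gene Lyz2 that can share its reads, at 1714 CPM in mutant 1 and 3397 to 6009 CPM elsewhere. The median macrophage gene was higher there by 3.34 on the log2 scale.

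Mutant 1 had 1092 genes at least 5-fold above each of the other libraries, against 0 to 3 genes in any other library. Its log2 CPM correlated with the other libraries at r = 0.914 to 0.937 across genes, where the remaining pairs gave 0.967 to 0.984 (genes are not independent replicates). Xist, the transcript of the inactive X chromosome, stood at 184.6 CPM in wild type 2, with the Y-linked gene Ddx3y at 2.88 CPM. In the other 5 libraries Xist was at most 2.93 CPM and Ddx3y was 49.8 to 78.2 CPM.

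The comparison of mutant with wild-type cells asked whether deleting Dlk1 in AT2 cells alters their expression during repair, in particular of Notch genes and of AT2 and AT1 genes. None of the 12 core Notch and alveolar genes passed the test, and all of them but Notch3 and Hey1 had log2 fold changes between -0.29 and 0.30. The extracellular matrix genes Fbln5 and Aebp1, the chloride channel gene Ano1 and the growth factor gene Tgfb2 had the smallest p-values on the higher side, and Hes2, a repressor of the HES family, and the small X-linked genes Bex1, Bex2 and Bex4 on the lower side. None of these passed the threshold in edgeR. No gene of 12899 tested passed a Benjamini-Hochberg adjusted p of 5% in edgeR's quasi-likelihood test. At an unadjusted p under 0.05, edgeR gave 476 higher and 373 lower genes, where 645 are expected by chance. limma-voom with quality weights also called 0 genes (lowest adjusted p = 0.0775), but gave 614 higher and 676 lower genes at an unadjusted p under 0.05, more than edgeR. DESeq2 called 27 higher and 19 lower. Of the 27 higher genes, 16 were at least 5-fold above each other library in mutant 1. Of the 46 DESeq2 calls, 12 were called again with the same sign when mutant 1 was left out, when DESeq2 called 22 genes.

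Fbln5, which encodes a protein of elastic fibres, averaged 27.8 ± 1.44 CPM in the mutant and 14.8 ± 0.42 CPM in the wild-type libraries (SD, n = 3 each), a log2 fold change of 0.91 ± 0.09 (SE) with an edgeR adjusted p of 0.203. Aebp1 averaged 50.1 ± 5.24 against 31.5 ± 2.86 CPM and Ano1 80.9 ± 6.97 against 51.8 ± 5.83 CPM. Tgfb2, a ligand of the TGF-β receptors, averaged 3.90 ± 1.03 against 0.69 ± 0.26 CPM, with a log2 fold change of 2.50 ± 0.44 at this low level. Lrp4 averaged 63.8 ± 4.77 against 45.8 ± 1.92 CPM. Hes2 averaged 7.18 ± 1.88 CPM in the mutant and 21.6 ± 5.93 CPM in the wild-type libraries, a log2 fold change of -1.59 ± 0.26. Bex2 averaged 130.5 ± 13.5 against 200.02 ± 13.7 CPM, Bex4 68.8 ± 7.31 against 104.7 ± 8.51 CPM and Bex1 4.08 ± 0.17 against 8.97 ± 1.14 CPM. The Bex genes are paralogs, and how reads shared between them were counted is not given in the sources used here. Tmem154 averaged 40.3 ± 4.76 against 60.9 ± 2.79 CPM. These last 9 genes each had an edgeR adjusted p of 0.737. In each of the 10 genes, the 3 mutant libraries did not overlap the 3 wild-type libraries. Over all tested genes, 11.7% did not overlap, where 10% is the share that chance gives for 3 against 3.

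All of these genes except Lrp4 were among the 12 that DESeq2 called both with all 6 libraries and without mutant 1. The higher ones were Fbln5 (DESeq2 adjusted p = 3.6e-07 with all libraries), Tgfb2, Aebp1 and Ano1. The lower ones were Bex2, Hes2, Bex4, Bex1, Tmem154, the ectonucleotidase gene Entpd1, the MAP kinase phosphatase gene Dusp4 and the calcium channel gene Trpv6.

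**Figure D1:**
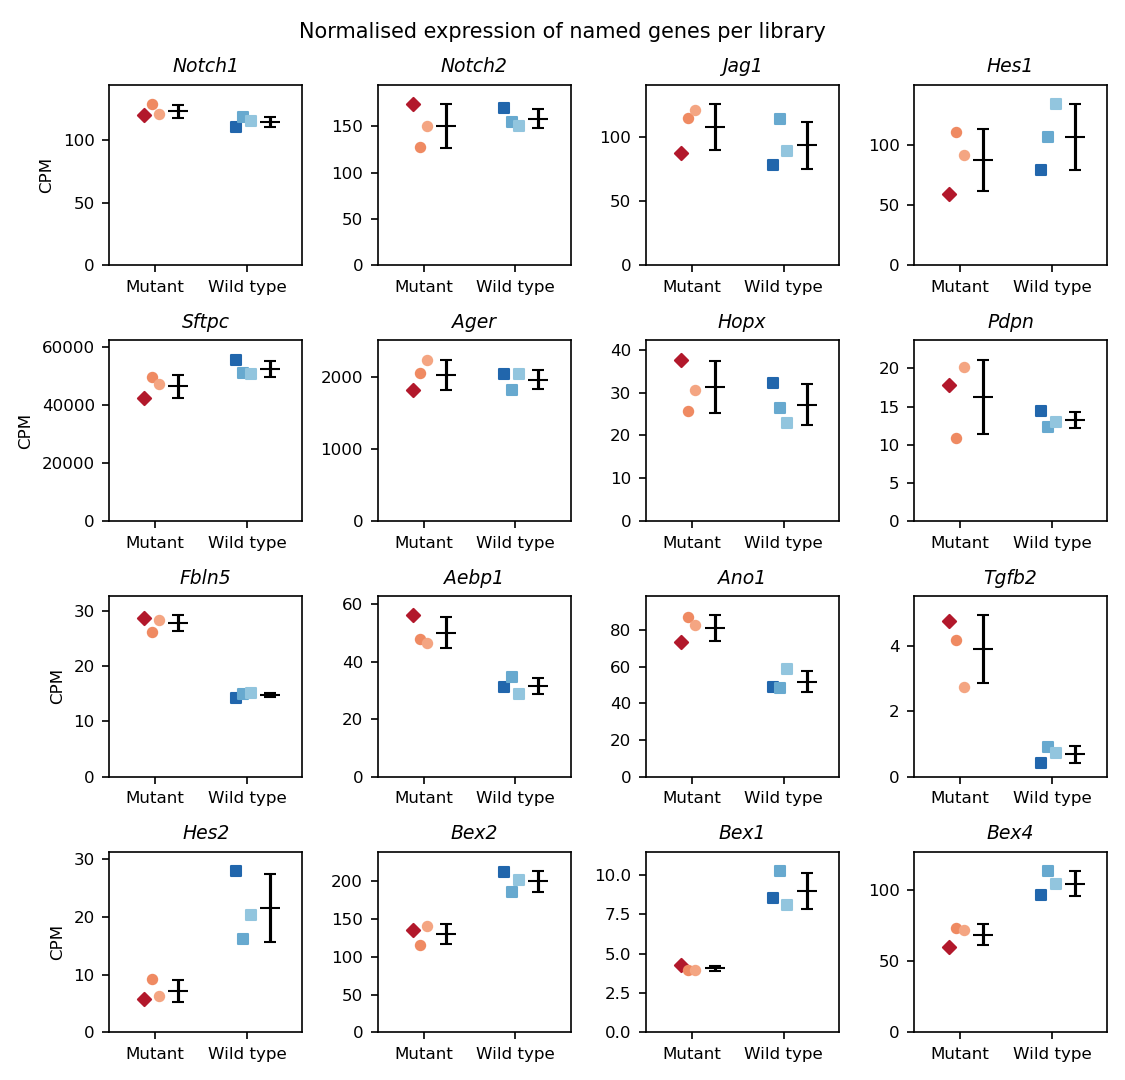
TMM-normalised CPM of 16 named genes (linear axes from 0), 1 symbol per library with the mean and SD of each group of 3 beside it, mutant 1 as a diamond. The Notch genes and alveolar markers in the upper rows overlap between the groups or lie close together, and the genes in the lower rows, such as Fbln5 at 27.8 against 14.8 CPM, do not overlap.

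Notch genes were examined as the pathway in which Dlk1 acts. Notch1 averaged 123.02 ± 5.12 CPM in the mutant and 114.4 ± 4.15 CPM in the wild-type libraries, a log2 fold change of 0.10 with a 95% interval of -0.06 to 0.27. Notch2 differed by -0.07 (-0.36 to 0.21), the ligand gene Jag1 by 0.21 (-0.20 to 0.61) and the target gene Hes1 by -0.29 (-0.90 to 0.33). For Notch1 and Notch2 the intervals left room for changes of under 1.5-fold only, while Jag1 and Hes1 were measured less tightly. Leaving out mutant 1 moved the log2 fold changes to 0.13 for Notch1, -0.19 for Notch2, 0.34 for Jag1 and -0.07 for Hes1. Notch3 had a log2 fold change of 1.44, with 276 counts in mutant 1 and 20 to 38 in the other 5 libraries, and its sign turned to -0.21 under limma-voom. Hey1 had at most 14 counts in any library but mutant 1, which had 65. Of 28 tested Notch pathway components, 17 had a positive and 11 a negative log2 fold change, and none passed the threshold. The list's median was 0.05 and its camera adjusted p was 0.197 (0.0005 and 0.627 without mutant 1). Of its members, Maml3 (-0.27 ± 0.08), Ncstn (0.20 ± 0.06), Adam10 (0.32 ± 0.11) and Lfng (3.51 ± 1.23, 12.4 CPM in mutant 1 alone) had the smallest p. The 8 tested Notch target genes had a camera adjusted p of 0.418.

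AT1 markers were higher in the mutant libraries as a list when compared with other genes, with 17 of 20 positive and a median log2 fold change of 0.19 (camera adjusted p = 0.00351 with the preset correlation). The call was lost with an estimated correlation (adjusted p = 0.43). The list's leading members were Akap5, an anchoring protein, at 35.8 ± 3.27 against 21.04 ± 5.29 CPM, and Cav1, the main protein of caveolae, at 25.9 ± 9.22 against 11.4 ± 2.84 CPM. In edgeR these 2 genes passed when adjusted over the list alone and 0 passed over all genes tested, while DESeq2 called Cav1 over all genes with all libraries (adjusted p = 0.0490) and not without mutant 1 (0.287). Cav1 is also an abundant endothelial transcript, and endothelial markers were far higher in mutant 1 and, at low levels, higher in mutants 2 and 3 than in the wild-type libraries as a list median. The classical AT1 genes had log2 fold changes (with 95% intervals) of 0.05 for Ager (-0.22 to 0.33), 0.20 for Hopx (-0.21 to 0.62), 0.30 for Pdpn (-0.23 to 0.84) and -0.19 for Aqp5 (-0.57 to 0.19). In the same order, they were 0.13, 0.05, 0.24 and -0.09 without mutant 1. Without mutant 1 the list kept its call and its median of 0.19, and without mutant 2 it was not called (adjusted p = 0.0576). The summed level overlapped between the groups, at 5642, 6137 and 6220 CPM in mutants 1, 2 and 3 and 5356, 5271 and 6244 CPM in wild types 1, 2 and 3. The median log2 ratio to the other 5 libraries did not, at 0.03, 0.13 and 0.05 in the mutants and -0.21, -0.15 and -0.08 in the wild types.

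AT2 markers were lower as a list, with 17 of 20 negative and a median of -0.16 (camera adjusted p = 0.0210, and adjusted p = 0.57 with an estimated correlation). Sftpc averaged 46460 ± 3816 CPM in the mutant and 52533 ± 2801 CPM in the wild-type libraries, a log2 fold change of -0.18 (-0.50 to 0.14). Cebpa, a transcription factor gene of AT2 cells, had -0.47 ± 0.14, the chemokine gene Cxcl15 -0.42 ± 0.15 and the mucin gene Muc1 0.25 ± 0.10. Without mutant 1, which held the lowest AT2 sum, the AT2 list had a median of -0.09 and was not called (adjusted p = 0.566), nor was it without wild type 1 (0.0548) or wild type 3 (0.0663). Transitional alveolar markers, the keratin-rich set seen between the AT2 and AT1 states, were evenly divided (10 positive, 10 negative, median 0.00, adjusted p = 0.933), and Krt8 differed by -0.07 (-0.53 to 0.38).

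Proliferation genes were higher as a list in the mutant libraries, with 24 of 26 positive and a median log2 fold change of 0.66 (camera adjusted p = 3.46e-07, and adjusted p = 0.43 with an estimated correlation). Mki67, the gene of the Ki-67 antigen, averaged 25.3 ± 9.0 against 10.7 ± 5.02 CPM. Top2a, a topoisomerase of dividing cells, averaged 16.8 ± 4.08 against 7.73 ± 3.50 CPM, and the cyclin gene Ccnb2 4.12 ± 0.66 against 1.87 ± 0.36 CPM. No member passed over all genes or adjusted over the list alone. Without mutant 1 the median was 0.44 and the list was still called (adjusted p = 2.89e-05), as it was without each of the other libraries. The summed level was 316, 243 and 331 CPM in mutants 1, 2 and 3 and 194, 223 and 279 CPM in wild types 1, 2 and 3, and Mki67 stood at 31.7, 15.02 and 29.3 against 5.44, 11.2 and 15.4 CPM. In both, the groups overlapped, with mutant 2 below wild type 3. Both were higher in each mutant than in the wild type of the same number, but that pairing was taken from these data alone.

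Lipid and secretory-pathway lists were lower in the mutant group. All 17 unfolded protein response genes were negative, with a median of -0.29 (camera adjusted p = 1.35e-05, and adjusted p = 0.43 with an estimated correlation), led by Xbp1 (-0.33 ± 0.11) and Asns (-0.51 ± 0.21). Of 18 cholesterol synthesis genes 17 were negative, with a median of -0.19 (adjusted p = 7.4e-06, and adjusted p = 0.43 with an estimated correlation), led by Dhcr7 (-0.34 ± 0.11) and Fdps (-0.32 ± 0.11). Of 19 fatty acid and phospholipid synthesis genes 17 were negative, with a median of -0.15 (adjusted p = 0.000357, and adjusted p = 0.43 with an estimated correlation), led by Acot7 (-0.43 ± 0.13) and Acly (-0.35 ± 0.13). No single member passed. Without mutant 1 the unfolded protein response median was -0.17 and still called (adjusted p = 0.00703), that of cholesterol synthesis was -0.10 (adjusted p = 0.0495), and fatty acid synthesis was not called (adjusted p = 0.138). Taken as the median log2 ratio to the other 5 libraries, cholesterol synthesis genes stood at -0.31, 0.10 and -0.17 in mutants 1, 2 and 3 and at -0.02, 0.08 and 0.22 in wild types 1, 2 and 3, so mutant 2 lay above wild types 1 and 2. Fatty acid synthesis genes stood at -0.22, 0.03 and -0.08 in the mutants and at 0.10, 0.09 and 0.01 in the wild types, so mutant 2 lay above wild type 3. Each mutant lay below the wild type of the same number, a pairing taken from these data alone. For the unfolded protein response wild type 1 stood apart at 0.31, with wild types 2 and 3 at -0.05 and -0.04 and mutants 1, 2 and 3 at -0.24, -0.11 and -0.05.

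MHC class II genes were higher as a list, with 6 of 8 positive and a median of 0.21 (camera adjusted p = 0.0124, and adjusted p = 0.43 with an estimated correlation). Ciita, the master regulator of these genes, averaged 96.02 ± 7.54 against 76.7 ± 5.90 CPM. The list was still called without mutant 1 (adjusted p = 0.0495), but not without mutant 3 (0.164) or wild type 3 (0.137). As the median log2 ratio to the other 5 libraries, mutant 2 (-0.05) lay below wild type 2 (-0.02). Antigen-presenting blood cells also express these genes, and their markers were high in mutant 1. The member H2-Eb1 stood at 271 to 375 CPM in mutants 1 and 2 and wild type 2 and at 507 to 618 CPM in the other 3 libraries, across the groups. In the opposite direction, H2-DMb2 stood at 46.0, 33.2 and 31.8 TMM-normalised CPM in mutants 1 and 2 and wild type 2. It stood at 5.21 to 13.4 CPM in the other 3 libraries. H2-Aa was also higher in mutants 1 and 2 and wild type 2 than in each other library. Part of the list thus followed these libraries and not the groups.

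A further 6 program lists were called with the preset correlation when all libraries were used, and not called without mutant 1 (adjusted p from 0.0553 to 0.26). Interferon response genes (median 0.41, adjusted p = 0.00434), basement membrane and integrin genes (0.15, 0.00823) and YAP targets (0.20, 0.0211) were higher, and lung epithelial transcription factors (-0.14, 0.00688), imprinted genes (-0.11, 0.0404) and Wnt targets (-0.19, 0.0477) were lower. Each of these had an adjusted p of 0.43 with an estimated correlation. Without mutant 1 the interferon median fell to 0.09 and that of YAP targets to 0.12. The interferon (0.195) and basement membrane (0.176) lists were also lost without wild type 3 and YAP targets (0.144) without wild type 1, while imprinted genes were called in 2 and Wnt targets in 1 of the 6 fits that left out 1 library (adjusted p up to 0.232 and 0.391). The mean of the Wnt targets was 0.12, opposite in sign to their median, with Tcf7 at 27.0 CPM in mutant 1. Tgfb2 was the single YAP target to pass when adjusted over the list alone, Lama3 (0.42 ± 0.11) led the basement membrane list, Ifi44 (2.06 ± 0.69, at 0.53 to 0.76 CPM against 0.05 to 0.20 CPM, near the floor) the interferon list, Gata6 (-0.25 ± 0.10) the transcription factors, Igf2 (-0.75 ± 0.27) the imprinted genes and Znrf3 (-0.35 ± 0.09) the Wnt targets. TGF-β targets (adjusted p = 0.0808), hypoxia and glycolysis genes (0.208), NF-κB targets and chemokines (0.655), immediate early genes (0.819) and p53 targets (0.851) were not called. For immediate early genes the median (-0.02) and the direction of the test (higher) differed in sign, and for p53 targets the median (0.05) and the test (lower) did.

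Of 8 tested lists of other cell types, 7 were called higher in the mutant group with the preset correlation, following mutant 1. Their median log2 fold changes were 2.68 for club and goblet cells, 2.10 for ciliated cells, 1.87 for macrophages and monocytes, 3.49 for lymphocytes, 2.73 for endothelial cells, 3.98 for fibroblasts and 3.27 for genes of all blood cells, with adjusted p-values from 0.000137 to 0.0430, and from 0.43 to 0.63 with an estimated correlation. Mesothelial genes had a median of 1.87 and were not called (adjusted p = 0.851). Without mutant 1, the endothelial list remained called as higher (median 0.45, adjusted p = 0.0495), with Vwf at 2.01 and 2.01 TMM-normalised CPM in mutants 2 and 3 and 0.32 to 0.87 CPM in the wild-type libraries and Calcrl at 0.56 and 0.85 against 0.16 to 0.28 CPM. Cdh5 stood at 0.51 and 1.59 against 0.16 to 0.50 CPM, so mutant 2 was level with the highest wild type. Pecam1 overlapped (2.05 and 1.34 against 1.08 to 1.46 CPM). As a sum over the list, mutant 2 (203 CPM) lay within the wild types (193 to 203 CPM), and mutant 3 stood at 223 CPM. The mesothelial list was called as lower without mutant 1 (adjusted p = 0.019), with Msln at 0.46 and 4.52 CPM in mutants 2 and 3 and 3.41 to 3.73 CPM in the wild-type libraries. With an estimated correlation neither was called without mutant 1 (adjusted p = 0.73 each).

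Over all 29 lists tested, 20 were called with the preset correlation, 13 higher and 7 lower, and 0 were called with an estimated correlation or by fry, whether directional or mixed. Without mutant 1, 7 lists were called, of which 6 were shared with the full set in the same direction (AT1, proliferation, MHC class II and endothelial higher, unfolded protein response and cholesterol synthesis lower). Without wild type 3, 10 lists were called. Proliferation, unfolded protein response, cholesterol synthesis and endothelial genes were the 4 lists called in the same direction whichever of the 6 libraries was left out.

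**Figure D2:**
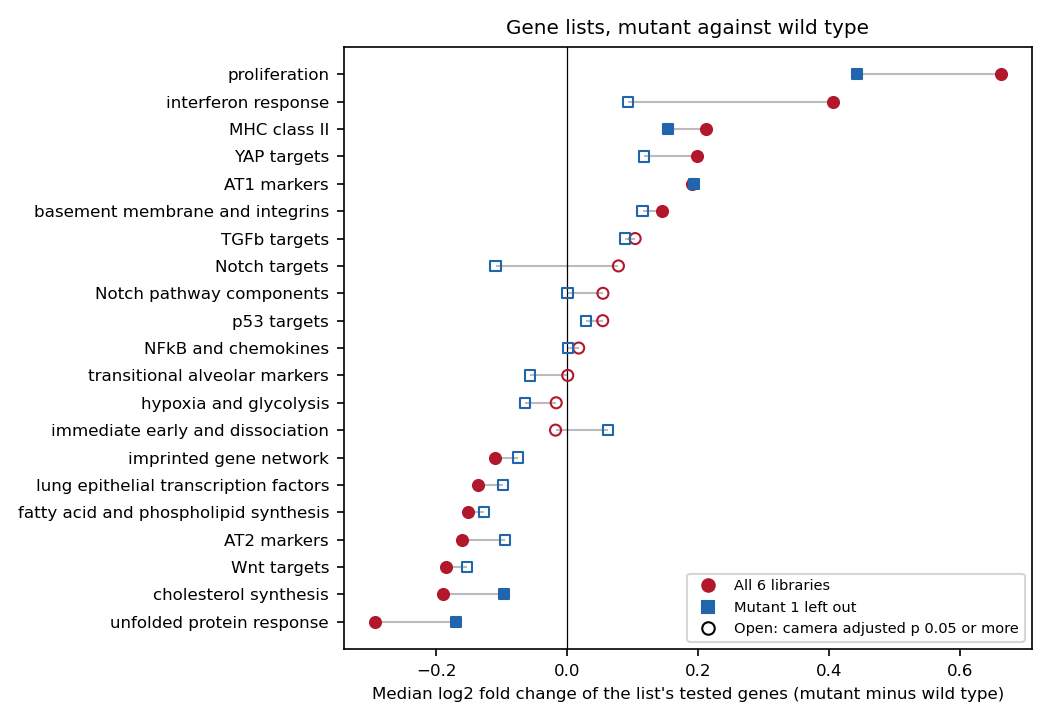
Median log2 fold change (mutant minus wild type) of the tested genes of each program list, with all 6 libraries (circles) and with mutant 1 left out (squares), filled where the camera adjusted p with the preset correlation was under 0.05. The proliferation median moves from 0.66 to 0.44, that of the AT1 list stays at 0.19, and that of the unfolded protein response moves from -0.29 to -0.17.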

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

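The fits that left out mutant 1 and wild type 2 together, and DESeq2 without mutant 1 or without both, were chosen after seeing the data. edgeR called 0 genes in either direction under the other scalings, both other filters and robust dispersion, limma-voom called 0, and so did edgeR with both libraries left out. DESeq2 called 27 higher and 19 lower genes with all libraries, 9 and 13 without mutant 1, and 9 and 8 without both. Leaving out 1 library at a time gave 0 to 1 higher genes in edgeR, the 1 being Gpr133 without wild type 3, and 0 lower genes. The replicate block gave 0 higher and 0 lower genes and 20 lists, and changed neither count. The number of lists called was 0 with an estimated correlation, 0 by fry, 8 with both libraries left out, and between 7 (without mutant 1) and 20 (without mutant 2) when 1 library was left out. Of these 20, 19 were among the 29 lists tested with all libraries and 1 was the neutrophil list, which had enough tested genes only in some of these fits. It was 10 without wild type 3 and 17 with the CPM filter. Without mutant 1, 14 of the 20 called lists lost their call. Of all lists 7 then turned from higher to lower, namely club cells (adjusted p = 0.282), ciliated cells (0.13), fibroblasts (0.894), mesothelial cells (0.019), transitional alveolar markers (0.901), Notch targets (0.656) and NF-κB targets and chemokines (0.901), and p53 targets turned to higher (0.90). With both left out, 7 turned to lower, namely club cells (0.256), ciliated cells (0.191), macrophages (0.892), fibroblasts (0.675), mesothelial cells (0.0467), Notch targets (0.519) and NF-κB targets and chemokines (0.976), and p53 targets turned to higher (0.519). Without wild type 1, immediate early genes turned to lower (0.00185). They were called as higher without wild type 2 (0.015) and with mutant 1 and wild type 2 both left out (0.00164). The cause of these opposite calls was not tested. Over the 6 fits with 1 library left out, the adjusted p ran from 0.00185 to 0.935 for immediate early genes, from 2e-04 to 0.299 for club cells, 2e-04 to 0.376 for ciliated cells, 0.00309 to 0.894 for fibroblasts and 0.019 to 0.942 for mesothelial cells. Of 132 named genes, 12 were called by DESeq2, 4 changed sign under limma-voom (Notch3 -0.21, Upk3b -0.36, Lrrn4 -0.80, Gpm6a -0.54), of which Gpm6a also did under the block (-0.05), and 13 did without mutant 1. Scaling moved the median log2 fold change of all genes by no more than 0.06. Dlk1 gave no value under any setting, being at or under the floor. For Dlk1 the limit is that the wild-type libraries held almost no transcript, at most 2 counts each. For Hey1 it is the low level, at 2 to 14 counts in each library but mutant 1, which had 65. The simulated recovery of 16.1% at 1.5-fold shows that small changes would mostly be missed with these libraries. It was 22.4% in a simulation without mutant 1, but with 14.2 false calls on average among 126.6, against 6.2 among 105.6 with all libraries. The 2 recoveries were thus not at a like rate of false calls. Whether the number of libraries was the only limit is not settled by them.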

Other observations

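The tests that leave out mutant 1 or wild type 2 and those on genes that part the libraries across the groups were chosen after the results were seen, as were the genes named in this part. Without mutant 1, DESeq2 called genes that it did not call with all 6 libraries, among them Tgfbi, Fn1, Bach2 and Nod1. For Fn1, DESeq2 gave no adjusted p with all 6 libraries, so it was not assessed there. Tgfbi, an adhesion protein of the extracellular matrix, stood at 30.9 and 29.2 CPM in mutants 2 and 3 and at 57.3 to 77.3 CPM in the wild-type libraries, with 72.4 CPM in mutant 1. Without mutant 1 its log2 fold change was -1.21 ± 0.14 (DESeq2 adjusted p = 3.26e-09, edgeR adjusted p = 0.376). Fn1, the fibronectin gene, stood at 9.67 and 13.9 CPM against 3.38 to 5.03 CPM, with 208.7 CPM in mutant 1, and the transcription factor gene Bach2 at 19.9 and 17.8 against 31.8 to 34.3 CPM, with 30.7 CPM in mutant 1. The innate immune receptor gene Nod1 stood at 26.6 and 30.04 CPM against 42.3 to 53.2 CPM, with 55.9 CPM in mutant 1.

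A set of 21 genes was higher in 2 to 4 libraries than in all the others, with a gap of at least 2 on the log2 scale, and none of them followed mutant against wild type. In the lower libraries some were near zero and others were not, such as Pak6 at 5.78 to 8.49 CPM against 37.04 and 43.5 CPM in mutant 1 and wild type 3. Several were in the major histocompatibility complex. H2-Ea-ps, the class II gene that is silent in C57BL/6 mice and others of the b haplotype, stood at 27.4, 21.6 and 22.9 CPM in mutants 1 and 2 and wild type 2 and at 0.31 CPM or less in mutant 3 and wild types 1 and 3. Gm8909 (78.7, 42.0 and 52.6 CPM against at most 1.32), H2-Bl, H2-Q1, H2-Q10, Btnl2 and 2410017I17Rik followed the same 3 libraries. Gpr133, an adhesion receptor gene, stood at 17.1, 17.4, 15.2 and 15.4 CPM in the 3 mutants and wild type 3 and at 0.22 and 0.28 CPM in wild types 1 and 2, and its neighbour Mmp17 followed it. Its call without wild type 3 (log2 fold change 5.99, edgeR adjusted p = 0.00636) rested on that pattern. Fbp1 and Fbp2, neighbouring paralogs of a gluconeogenic enzyme, were higher in mutants 2 and 3 and wild type 1, and Pgm5 was higher in mutants 1 and 2 and wild type 3.

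A candidate explanation is that the mice carried different strain segments. Of the 19 such genes with a place in the gene order, 11 had a neighbour within 50 detected genes with the same library pattern, where 10000 random placements gave at most 6 (permutation p = 1e-04, the smallest these can give). The pattern of H2-Ea-ps was held by 7 genes, all on chromosome 17. Linked genes are counted separately in this test, so 1 region supplied much of the count. Some of these neighbours are paralogs that can share reads, although Gpr133 and Mmp17, and Btnl2 and H2-Ea-ps, are not. Induction in the 3 libraries with H2-Ea-ps was weighed on 8 abundant MHC-related genes, of which Cd74, Ciita and B2m lie outside the complex. Only 1 of the 8 (H2-Aa) was higher in each of these 3 libraries than in each other library. H2-Eb1 was lower in them (271 to 375 CPM against 507 to 618 CPM). This argues against a rise of the 8 genes together. H2-DMb2, outside these 8 genes, was higher in them (31.8 to 46.0 against 5.21 to 13.4 TMM-normalised CPM). For H2-DMb2, H2-Ea-ps and the genes that followed it, induction stays open. Counts of H2 genes also depend on how reads of each allele align, which was not tested. The labels give no strain, and no biological explanation by Dlk1 was tested because the patterns cross the groups.

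The other-cell transcripts of mutant 1 may come from RNA of other lung and blood cells in that library, which the Tomato sort would be meant to remove. Of 41 further markers of lung and blood cells, none of them in the lists that showed the pattern, 32 (78%) had at least 10 counts in mutant 1 and lay at least 2-fold above each other library, against 2 of 38 markers of tissues outside the lung (5.26%), which a general rise of silent genes would have raised too. Among the 32, Blk and Msr1 were also DESeq2 calls high in mutant 1, so they add no independent evidence. An effect shared by the mutant mice is argued against, since mutants 2 and 3 both lay above all wild-type libraries in the median of 1 of the 9 lists of other cell types with at least 3 detected genes (endothelial). Depth is argued against as well, since after thinning every library to the smallest total mutant 1 still had 1352 more detected genes than the next. Whether the cells entered through the sort or the RNA was mixed later stays open.

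The higher AT1 and proliferation lists were weighed against other-cell RNA in mutant 1 as the whole cause. Without that library the median was 0.19 for AT1 genes and 0.44 for proliferation genes (0.66 with all libraries), so mutant 1 alone did not make the whole difference. Both kept their call and direction, with camera adjusted p = 0.00045 for AT1 genes and 2.89e-05 for proliferation genes under the preset correlation. That form called 8 to 20 lists in the other splits of the libraries, so a kept call decides little. The AT1 list also lost its call without mutant 2 (0.0576). With an estimated correlation neither was called (adjusted p = 0.58 and 0.73 without mutant 1). That correlation was 0.57 for proliferation genes, so shared variation among them stays open, and -0.02 for AT1 genes (unadjusted p = 0.0199), whose call was lost to the few degrees of freedom of the estimated form and the adjustment over lists. An effect of Dlk1 deletion stays open for both, as does a small share of endothelial RNA in mutants 2 and 3 for Cav1 in the AT1 list.

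With 10 splits of the libraries a share under 0.05 cannot be reached for these medians. The real split gave the largest AT1 median (1 of 10, 0.19 against 0.18 at most elsewhere), and 2 of 10 splits gave a proliferation median as large (0.66, highest other 0.71 in a split that parts 1 numbered pair). Among the 4 splits that part all 3 numbered pairs, the highest others were 0.09 for AT1 and 0.37 for proliferation genes. The pairing was taken from these data alone and 4 splits can show less than 10, so this decides nothing.

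The same limit of 10 splits holds for the counts of calls. For genes past 5% in edgeR the real count of 0 is reached by all 10 splits whatever they give, so it decides nothing (highest other 5). At an unadjusted p under 0.05, 4 of 10 splits gave at least the real 849 genes (highest other 1238), for DESeq2 4 of 10 gave at least 46 (highest other 111), and for lists 2 of 10 gave at least 20 (highest other 20, lowest 8). The split with 1238 and 111 genes set mutant 1 and wild types 1 and 2 against the rest and parted 1 numbered pair. Among the 4 splits that part all 3 numbered pairs, as the real one does, the highest others were 425 genes, 11 DESeq2 calls and 20 lists. Since the labels give no pairs and 4 splits can show less than 10, no conclusion is drawn from these 4.

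Leaving out mutant 1 gave 0 genes past 5% in edgeR, with 390 higher and 368 lower at an unadjusted p under 0.05, although the biological coefficient of variation estimated by edgeR dropped from 0.307 to 0.174. Of the 10 genes with the smallest p, 10 kept their sign and an unadjusted p under 0.05 without wild type 2, the library with the female pattern. This outcome was close to fixed, since the genes were picked for their small p in the same libraries. The 100 tested genes nearest Dlk1 held 7 genes with an unadjusted p under 0.05, and 0.451 of all windows of 100 neighbouring genes held as many or more (median 6, highest 19).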
